A study of Mus musculus with 70 samples.

How the data were processed

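Bulk RNA sequencing was done on mouse medulloblastomas, cerebellar tumours of the Sonic hedgehog (SHH) type, from 2 models. Per the labels, RNA was polyadenylated RNA taken with the RNeasy kit, and libraries were made with the TruSeq RNA kit. Per the submitters' processing notes, STAR 2.5.4b and the genome build mm9 were named, without their role or order. The program that counted reads per gene, its use of strand and its annotation are not given in the sources used here. The authors deposited 1 table of counts per model, and the values are whole-number read counts per gene, not normalized. The table of the Math1-Cre; SmoM2 tumours held 53379 rows and 10 libraries. The table of the Lazy Piggy tumours held 37964 rows and 60 libraries, 10 rows of which name parts of the transposon construct and no mouse gene. Those rows took 0.00120% of the reads, stayed out of the library sizes and gene tests, and were compared apart. Gene symbols came from a GENCODE M21 name table, an annotation of GRCm38. It matched 53274 rows with 99.99% of the counts in the first table, and 32882 rows with 99.3% of the counts in the second. Unmatched rows were tested under their identifiers. The annotation was used for names and for which genes neighbour Kcnb2, and no coordinates are given, since its build is another than the one the notes name.

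Total counts per library ran from 23923453 to 39387125 in the first table and from 5869618 to 8667344 in the second. No pair of libraries had counts alike within sampling noise: over genes with a mean of 50 counts or more, the chi-square statistic per degree of freedom was at least 36.0 for the 45 pairs of the first table and at least 8.89 for the 1770 pairs of the second. Groups were taken from the genotype and treatment labels. These gave 7 wild-type and 3 Kcnb2 knockout tumours in the first model, and 29 tumours with and 30 without tamoxifen in the second. A tumour without a treatment label was left out of every comparison. The labels do not say whether tumours came from separate mice, although titles hold mouse numbers or dates, so p-values measure the spread between these libraries. Replicates were numbered in accession order, which pairs nothing. Sex was read from the Y genes Ddx3y, Uty, Kdm5d and Eif2s3y, with over 10 reads-per-million (RPM) marking a male.

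Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter (smallest count 10) and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Knockout was tested with the form of the title as a covariate, because all 3 knockouts have titles that start with a number, as do only 3 of the 7 libraries labelled wild-type. That contrast lies within those 6 libraries, 3 against 3. Tamoxifen was tested without covariates. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Log2 CPM (counts-per-million) used a prior count of 2, and a list's score in a library is the mean log2 CPM of its genes. On simulated data with the real means and library sizes and 200 changed genes, the knockout fit recovered 28% of 2-fold and 80% of 4-fold changes over 19560 genes, with 7 false calls among 115. The tamoxifen fit recovered 78% of 1.5-fold and 92% of 2-fold changes over 13674 genes, with 12 false calls among 182.

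Before the data were examined, 22 gene lists were fixed: Hedgehog targets, cell cycle, stem and progenitor, granule neuron differentiation, potassium channels, EGFR and ERK feedback, cell volume and osmotic response, p53 targets, immediate early and stress, interferon response, hypoxia, oestrogen response, sex-linked genes, and markers of astrocytes, microglia and macrophages, T and NK cells, endothelium, pericytes and fibroblasts, oligodendrocytes, Purkinje cells and interneurons, choroid plexus and red cells. Lists with 5 or more tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the lists. Camera compares a list with all other genes, and fry asks whether the list's genes move one way on balance. Also fixed then were the designs, the outlier and spread measures, the rule for named genes, and the alternatives except those said below to be chosen after seeing the data. The rule names Kcnb2, the 10 genes up and 10 genes down with the largest absolute log2 fold change among those past the threshold with a mean log2 CPM of at least 1 and no predicted or clone symbol, and for each list up to 4 members past the threshold with the smallest p. With fewer than 5 genes past it, the 10 with the smallest p are named as not passing.

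A gene was called an outlier in a tumour when it lay above the median of the 59 tumours by over 2 on the log2 CPM scale and by over 5 scaled median absolute deviations. Spread was the root mean square distance of a tumour to its group's mean over the 2000 genes of highest variance. Both were compared with two-sided permutation tests of 100000 resamples, as were the transposon RPM, a test added after the data were seen. Also added then, the mean CPM of Kcnb2 alone was compared between knockout and wild-type libraries over every split, as an exact two-sided permutation test. Alternatives covered DESeq2 1.42.0 and its size factors, limma-voom with quality weights, no low-count filter, the covariates, sex, the title dates, 10 surrogate variables (sva 3.50.0), a stricter threshold and left-out libraries. The precision of a gene's value is limited by its counts, and the second table is the shallower.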

Results

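RNA was sequenced from 70 mouse SHH medulloblastomas of 2 models. In the first, Math1-Cre switches on SmoM2, an active form of the Hedgehog transducer Smoothened, in granule neuron progenitors. There 7 tumours were labelled Kcnb2 wild-type, with 23923453 to 33959857 counts per library, and 3 were labelled Kcnb2 knockout, with 32838448 to 39387125. In the second, Ptch1 tumours carried Lazy Piggy, a transposon that the SB100 transposase mobilizes first and that the tamoxifen-dependent piggyBac transposase PBERT2 can mobilize again. Of these, 29 came from the tamoxifen group, with 6256214 to 8470896 counts, and 30 from the group without tamoxifen, with 5869618 to 8667344. One more tumour, with 7555740 counts, had no treatment label. Kcnb2 encodes a voltage-gated potassium channel subunit, and the series title names potassium channels in the upkeep of these tumours.

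The first comparison asked how tumours without Kcnb2 differ from tumours with it. Kcnb2 (ENSMUSG00000092083) itself was measured first, since it checks the labels. The knockouts had 11.5 ± 2.06 CPM (counts-per-million, mean ± SD, n = 3), and reads of the gene remained in each, at 9.91 to 13.8 CPM. Of the 7 libraries labelled wild-type, 6 had 22.5 to 50.5 CPM, with a mean of 36.8 ± 10.3 (SD, n = 6). The library labelled wild-type replicate 3 had 8.30 CPM from 281 reads, the lowest of all 10. Its title carries the ending that the titles of the knockouts carry, while its genotype field and its count column read wild-type. It stands below as the library labelled wild-type replicate 3, and each direction given for this comparison counts it as its genotype field does. With it, Kcnb2 had a log2 fold change of -1.38 ± 0.51 (SE), and edgeR's adjusted p over all genes was 0.566. Without it the change was -1.82 ± 0.32 (adjusted p = 0.838 in edgeR), and counted as a knockout it gave -1.94 (adjusted p = 0.676 in edgeR). Over all settings and left-out libraries its adjusted p ran from 0.0778 to 0.983. For this gene alone, exact two-sided permutation tests of the mean CPM, chosen after these values were seen and without the title form, gave p = 0.0583 as labelled, 0.0119 without that library and 0.00952 with it as a knockout. Taking the lowest library out of the wild-types favours a small p, and 0.0119 is the smallest that 84 splits can give. These tests also leave out sex. As labelled and with sex as a covariate, the change was -1.04 ± 0.46 (unadjusted p = 0.0506 in edgeR). Without sex, edgeR's unadjusted p was 0.0230 as labelled, 0.000251 without that library and 5.98e-05 with it as a knockout. There, too, moving the lowest library out of the wild-types favours a small p.

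**Figure D1:**
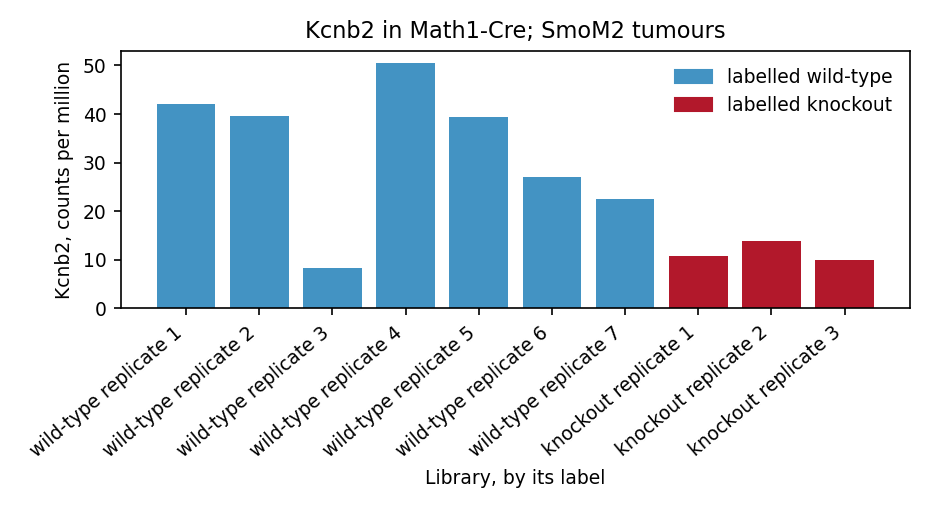
Bars give Kcnb2 in counts-per-million (CPM) in each of the 10 Math1-Cre; SmoM2 libraries, by label. The library labelled wild-type replicate 3, at 8.30, lies below all 3 knockouts (9.91 to 13.8), while the other 6 wild-type libraries lie between 22.5 and 50.5.

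Markers of pericytes and fibroblasts, the cells of vessel walls and connective tissue, were lower as a group in the knockouts by camera and not by fry (adjusted p = 0.0621 in fry). Their median log2 fold change was -0.66, 13 of 14 measured members were negative, and camera's adjusted p was 8.1e-07, and 0.0357 with an estimated correlation. Without the library labelled wild-type replicate 3 the adjusted p = 0.0727 with an estimated correlation, and with it as a knockout 0.464, so this call rests on that library's label. None of the 14 passed over all genes, and 2 passed adjusted over the list alone, Col3a1 and Lum. The collagen Col3a1 had -1.68 ± 0.45 (SE) and the proteoglycan Lum -1.66 ± 0.48 on the log2 scale. The vessel wall channel genes Abcc9 and Kcnj8 had -0.87 ± 0.28 and -0.70 ± 0.26, and all 4 had an adjusted p of 0.566 over all genes in edgeR. Of the 7 libraries labelled wild-type, replicate 1 had the lowest score of this list, 3.75, close to the knockouts' mean of 3.54 ± 0.14 (SD, n = 3).

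Other lists were called at camera's preset correlation and lost the call with an estimated one. Cell cycle genes were lower, with a median log2 fold change of -0.41 and 37 of 39 members negative (adjusted p = 6.5e-15, and adjusted p = 0.595 with an estimated correlation). Hedgehog targets had a median of -0.28 with 15 of 17 negative. Granule neuron differentiation genes, which mark the exit of these progenitors from division, had a median of 0.78 with 24 of 30 positive, and potassium channel genes 0.36 with 47 of 64 positive. Oligodendrocyte markers had a median of 1.72 with 11 of 11 positive, Purkinje and interneuron markers 1.55 with 13 of 14 positive, and choroid plexus markers -1.39 with 7 of 7 negative. For these 5 lists and Hedgehog targets, too, the adjusted p = 0.595 with an estimated correlation. Microglia and macrophage markers had a median of -0.36 with 16 of 19 negative, and adjusted p = 0.667 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone. The 3 knockouts also differed among themselves. Cell cycle scores were 6.33, 6.18 and 6.87 in knockout replicates 1 to 3, against 6.71, 6.92 and 6.92 in wild-type replicates 1 to 3. In the same order, granule neuron scores were 7.80, 8.16 and 7.15 against 7.39, 6.35 and 6.64. Oligodendrocyte scores were 6.94, 6.00 and 4.39 against 3.46, 2.97 and 5.49. Knockout replicate 3 thus lay within the range of these wild-type libraries, for causes not tested. Without the library labelled wild-type replicate 3, the choroid plexus and microglia lists lost their call at the preset correlation, and astrocyte markers and sex-linked genes gained one. With that library counted as a knockout, the granule neuron, potassium channel, microglia and choroid plexus lists lost it, while astrocyte and interferon lists gained it. Choroid plexus markers were also not called without knockout replicate 3, nor microglia markers without knockout replicate 2.

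The lists not called were stem and progenitor (median log2 fold change -0.05), EGFR and ERK feedback (0.01), cell volume (-0.08), p53 targets (-0.02), immediate early genes (0.09), interferon response (0.04), hypoxia (-0.07), oestrogen response (-0.29), astrocytes (0.23), endothelium (-0.16), red cells (0.75) and sex-linked genes (5 of 5 negative, adjusted p = 0.226 in camera). No median is given for the last, since the knockouts, all female, had almost no reads of its 4 Y genes, while Xist, its other member, had a log2 fold change of -0.05. The tests of EGFR and interferon genes, based on means, pointed down although these medians lie above 0. T and NK cell markers had 3 measured members, too few to test, with a median of -0.15, and 1 passed as lower adjusted over the list alone. Of the 7 libraries labelled wild-type, 4 were female.

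**Figure D2:**
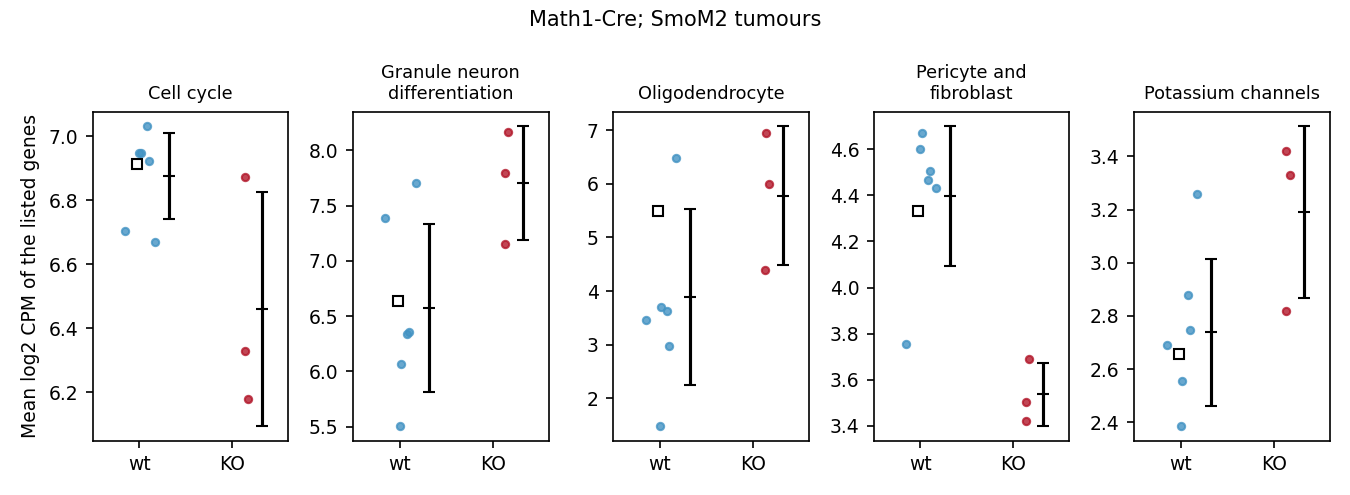
Points are list scores (mean log2 CPM of the listed genes) of the 7 libraries labelled wild-type (wt) and the 3 knockouts (KO), with group mean and SD beside them, and the square is the library labelled wild-type replicate 3. In the pericyte and fibroblast panel the knockouts average 3.54 and the lowest library labelled wild-type, replicate 1, lies at 3.75.

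No single gene passed the threshold in edgeR among 19864 tested. At an unadjusted p under 0.05 there were 1683 genes, 890 higher and 793 lower in the knockouts. DESeq2 called 4 genes up and 5 down. Its 5 down were the Y genes Eif2s3y, Ddx3y and Kdm5d (log2 fold changes -26.4, -26.3 and -25.6), Gm29650 and Pttg1. Gm29650 had a change near that of the Y genes (-23.7), and all 3 knockouts were female, so its call cannot be told from sex. Pttg1, which encodes securin, had -1.14. Its 4 up were Lyrm7, Synpo, Slc16a5 and Gm45844. The 10 genes with the smallest p in edgeR, none of them past the threshold (adjusted p = 0.566 each), were Slc16a5, a monocarboxylate transporter family gene (log2 fold change 2.54), Lyrm7 (1.64), Pttg1 (-1.13), Pald1 (-0.66), Gm45844 (1.36), Synpo (1.20), Gm4784 (-1.53), Adgrb1, an adhesion receptor (0.98), Rbp4, a retinol carrier (-1.13) and Mycl, a Myc family gene (-0.56). In the simulation this fit found 80% of 4-fold and 28% of 2-fold changes. Each gene was drawn on its own there, without shifts shared between genes, so real changes of these sizes may be harder to find.

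The second comparison asked how tumours given tamoxifen differ from those not given it. Markers of oligodendrocytes, astrocytes, and Purkinje cells and interneurons were higher in the tamoxifen group by camera at its preset correlation and by fry. None of these camera calls held with an estimated correlation (adjusted p = 0.0818 for oligodendrocytes and for astrocytes, 0.158 for Purkinje cells and interneurons). The granule neuron list was not called, with 16 genes positive and 13 negative. Of 13735 genes tested in edgeR, 420 were higher and 81 lower. The 10 named for the largest rise were the myelin genes Mog (2.31 ± 0.55, log2 fold change ± SE) and Mobp (2.69 ± 0.68), the Purkinje cell genes Pcp2 (2.40 ± 0.68), Car8 (2.36 ± 0.62), Calb1 (2.39 ± 0.71) and Ppp1r17 (2.64 ± 0.69), the neurofilament Nefh (2.20), the sodium channel subunit Scn4b (2.18), the G protein subunit Gng13 (2.15) and the enkephalin precursor Penk (2.31), with adjusted p from 0.0149 to 0.0429. Without tamoxifen replicate 14, Mog alone of these 10 kept its call (adjusted p = 0.0482), and the others had adjusted p from 0.0648 (Penk) to 0.199 (Nefh) in edgeR. All 10 rises were smaller without it, from 1.52 for Nefh and 1.71 for Car8 to 2.31 for Mobp, with Pcp2 between Calb1 (1.77) and Penk (1.87). Mobp averaged 68.2 ± 114 CPM with tamoxifen (SD, n = 29) and 10.6 ± 20.3 without (SD, n = 30), so the spread between tumours was wide. Calb1 was above the median of the other group in 23 of 29 tamoxifen tumours.

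Oligodendrocyte markers rose in 9 of 10 measured members, and in 10 adjusted over the list alone, with a median of 1.43. Mbp, a myelin protein gene, changed by 1.23 ± 0.27 (adjusted p = 0.0119 in edgeR), from 125 ± 64.8 to 293 ± 345 CPM (SD), Mal by 1.33 ± 0.29 and Cnp by 1.12 ± 0.24. Of Purkinje and interneuron markers 7 of 10 rose, and 9 adjusted over the list alone, with a median of 1.96. Among them was Pvalb (1.75 ± 0.49), a calcium-binding protein gene. Astrocyte markers rose in 6 of 12, and in 11 adjusted over the list alone, with a median of 0.79. They included Aldoc (1.56 ± 0.39), which Purkinje cells also express, S100b (0.93 ± 0.23), the gap junction gene Gja1 (0.92 ± 0.24) and Slc4a4 (0.78 ± 0.21). Interferon response genes rose in 7 of 14, and in 9 adjusted over the list alone, with all 14 positive and a median of 0.62. Rtp4 changed by 1.19 ± 0.24 (adjusted p = 0.00509 in edgeR), Ifit3 by 1.04 ± 0.23, Irf7 by 1.11 ± 0.30 and Ifit1 by 1.02 ± 0.28. Interferon genes were also called by camera at its preset correlation and by fry, and that camera call did not hold with an estimated correlation (adjusted p = 0.129).

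Camera also called cell cycle, potassium channel and microglia genes at the preset correlation. Cell cycle genes had a median of -0.08, 34 of 39 negative and none past the threshold (adjusted p = 0.980 with an estimated correlation). Potassium channels had a median of 0.15, and Kcng4 (2.10 ± 0.50), Kcna6 (1.13 ± 0.30) and Kcnc4 (1.77 ± 0.51) rose among 46 measured, 5 adjusted over the list alone (adjusted p = 0.702 with an estimated correlation). Without tamoxifen replicate 14 none of the 3 was called, and their rises were at most 1.52 (Kcnc4). Microglia markers had a median of 0.12, with P2ry12 (0.71 ± 0.20) alone past the threshold among 19, as when adjusted over the list alone (adjusted p = 0.980 with an estimated correlation).

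**Figure D3:**
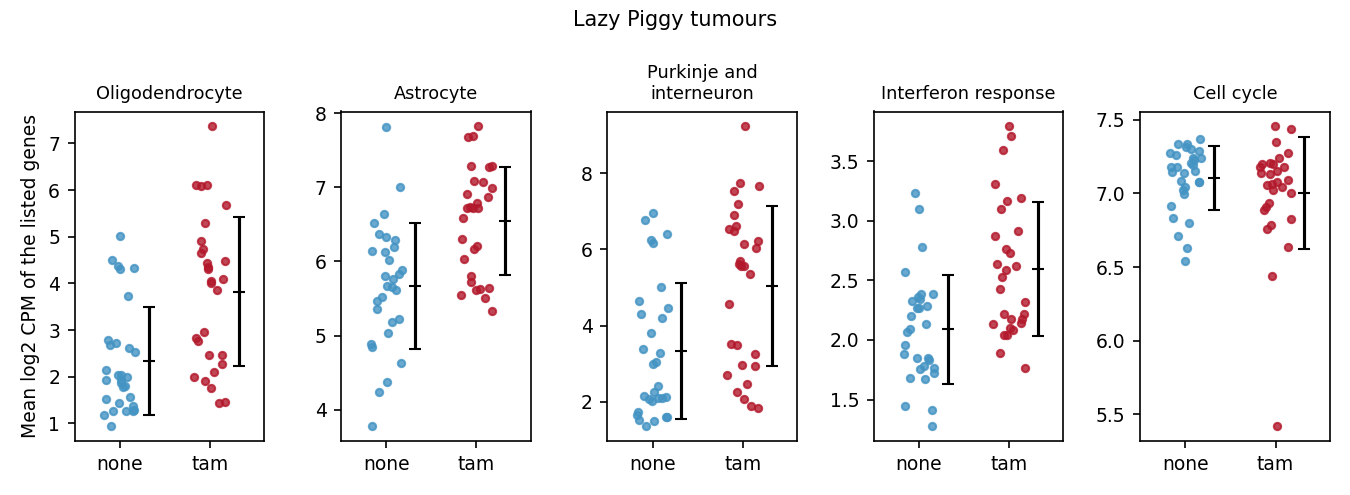
Points are list scores (mean log2 CPM of the listed genes) of the 30 tumours without (none) and the 29 with tamoxifen (tam), with group mean and SD beside them. The oligodendrocyte score averages 2.34 without and 3.83 with tamoxifen, and tamoxifen replicate 14 is highest there at 7.37 and lowest for cell cycle at 5.42.

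The remaining lists were not called. Hedgehog targets had a median of -0.01, and 1 of 17 rose, Hsd11b1 (1.55 ± 0.36), a glucocorticoid-activating enzyme. Stem and progenitor genes had a median of -0.01 and granule neuron differentiation genes 0.01, with none past the threshold. The granule neuron genes went both ways, 16 up and 13 down. They ran from Vsnl1 (1.84), Gabra6 (1.71) and Cbln3 (1.70) to Dcx (-0.31) and Cntn2 (-0.44). EGFR and ERK feedback genes had a median of -0.03, with the ligand gene Hbegf up (0.58 ± 0.13) and the phosphatase Dusp4 down (-0.56 ± 0.13). The cell volume list had a median of 0.04, with the kinase Sgk1 up (0.63 ± 0.16) and the stretch channel Piezo2 down (-0.92 ± 0.27). Of p53 targets (median -0.07) Plk3 fell (-0.41 ± 0.12), and of hypoxia genes (median -0.07) Ndrg1 (0.91 ± 0.23) and the glucose transporter Slc2a1 (0.41 ± 0.12) rose. Adjusted over each list alone, Dusp4 was joined by 1 more fallen gene in the EGFR list and 1 hypoxia gene fell, while the Hedgehog, cell volume and p53 counts were equal to those over all genes. Oestrogen response genes, listed because tamoxifen binds oestrogen receptors, had a median of 0.01 over 8 measured members. The medians were 0.07 for immediate early genes, -0.08 for endothelium, where 2 genes rose adjusted over the list alone, -0.10 for pericytes and fibroblasts, -0.17 for choroid plexus and -0.24 for sex-linked genes. Red cell markers (0.39, 3 measured) and the 1 measured T and NK cell gene (-0.69, lower adjusted over the list alone) were too few to test.

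Of the 10 named genes with the largest fall, several rested on single tumours. Tle6, a Groucho family co-repressor gene, had a log2 fold change of -3.80 ± 0.66 (adjusted p = 0.000808 in edgeR), which became -0.43 without no tamoxifen replicate 3 (adjusted p = 0.168). Foxd1 (-2.12) lost its call without no tamoxifen replicate 21 (-1.23, adjusted p = 0.0975 in edgeR) and changed sign in DESeq2 (0.10). Ccdc33 (-1.64) lost it without no tamoxifen replicate 6 (-0.67, adjusted p = 0.0507). The sodium channel subunit Scnn1a (-0.89 ± 0.19), the water channel Aqp5 (-1.27 ± 0.29), Ky (-0.67 ± 0.16) and C2cd4c (-0.61 ± 0.16) kept it with any 1 tumour left out. Lrrc55 (-0.84), Epb41l4a (-0.85) and Piezo2 lost it in 8, 10 and 12 of the 59 such fits, up to adjusted p of 0.0734, 0.0698 and 0.124. Any fit in which the low-count filter dropped the gene counts as lost.

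Kcnb2 did not differ detectably with tamoxifen. It averaged 6.74 ± 2.55 CPM (SD, n = 29) against 7.29 ± 2.47 (SD, n = 30), with a log2 fold change of -0.11 ± 0.14 (adjusted p = 0.685 in edgeR). The change was 0.35 among the earlier-dated titles and -0.37 among the later-dated ones, and the difference between these title periods was -0.72 (unadjusted p = 0.0110, and adjusted p = 0.999 over all genes in edgeR).

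**Figure D4:**
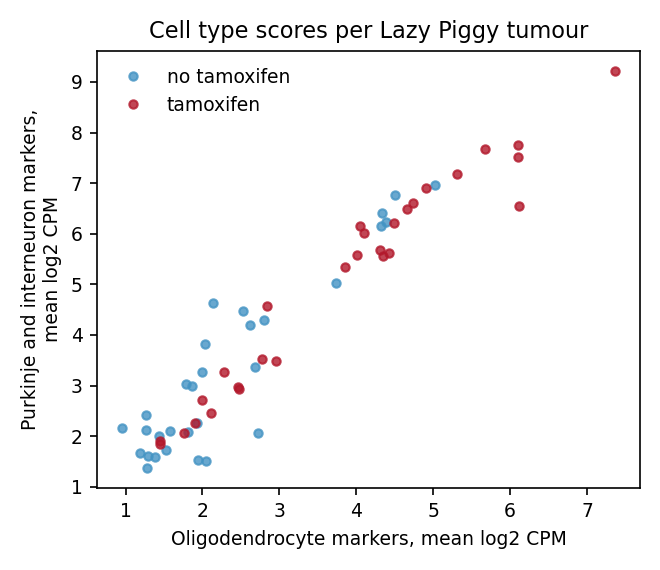
Each point is a Lazy Piggy tumour, with its oligodendrocyte score on the horizontal and its Purkinje and interneuron score on the vertical axis, both mean log2 CPM. The scores go together in both groups (Pearson r = 0.976 with and 0.917 without tamoxifen).

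Across tumours the markers of the separate cerebellar cell types moved together. Oligodendrocyte and Purkinje scores had a Pearson r of 0.976 in the tamoxifen group (n = 29) and 0.917 in the other (n = 30). Spearman's rho was 0.973 and 0.754. The permutation p of each r was 1e-05, the smallest 100000 permutations can give, also after adjustment over 6 relations, and that of the rhos was 1e-05 and 2e-05. Leaving out the 2 tumours farthest from the median oligodendrocyte score gave r of 0.969 and 0.883. Within the earlier and later titles r was 0.988 (n = 14) and 0.960 (n = 15) with tamoxifen, and 0.920 (n = 10) and 0.918 (n = 20) without. Tamoxifen replicate 14 had the highest oligodendrocyte (7.37), Purkinje (9.22) and astrocyte (7.82) scores and the lowest Hedgehog target (5.89) and cell cycle (5.42) scores of the 59. Without it 110 genes were higher and 28 lower, and 18 of the 45 named genes past the threshold kept their call. Then 7 oligodendrocyte, 3 interferon, 0 astrocyte, 0 Purkinje and 0 potassium channel genes rose over all genes, and 9, 9, 11, 9 and 3 adjusted over the list alone. P2ry12, Sgk1, Ndrg1, Slc2a1, Plk3 and Piezo2 also lost theirs, as did the list Cell cycle (adjusted p = 0.0923 in camera). Of the named genes that rose, Calb1, Nefh, Slc2a1 and Irf7 lost their call most often, in 28, 25, 17 and 12 of the 59 fits with 1 tumour left out. These counts include any fit in which the low-count filter dropped the gene. Microglia and macrophage markers as a list lost their call without tamoxifen replicate 19 (adjusted p = 0.0626) and without no tamoxifen replicate 16 (0.0514). Higher counts fell to 227, 254 and 269 without tamoxifen replicates 17, 19 and 20, and rose to 682 without no tamoxifen replicate 11.

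Titles of these tumours carry dates, and the earlier-dated ones were 14 of the 29 tamoxifen tumours and 10 of the 30 others. Within the later titles the tamoxifen tumours tended to carry the earlier dates, which a division into 2 periods does not take up. With the title period as a covariate 497 genes were higher and 65 lower, and 42 of the 45 named genes stayed past the threshold. Plk3, Piezo2 and Foxd1 did not (adjusted p = 0.0537, 0.0570 and 0.131 in edgeR). Within the earlier titles alone edgeR called no gene, with 1713 genes at an unadjusted p under 0.05, and within the later ones it called 2, Scd2 and Ddc, both up. The median changes of the oligodendrocyte, astrocyte and Purkinje lists were 1.49, 0.74 and 2.33 in the earlier and 1.44, 0.86 and 1.92 in the later titles. With 10 surrogate variables as covariates 9 genes were higher and 2 lower, none of the 45 named genes remained past the threshold, and the medians of these 3 lists were 0.62, 0.16 and 0.24.

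Because insertions differ between tumours, changes in few tumours were counted too. Tumours had 5.24 ± 18.2 outlier genes with tamoxifen (SD, n = 29) and 3.87 ± 10.2 without (SD, n = 30), a difference within the spread (two-sided permutation p = 0.794, and 0.799 within title periods). Tamoxifen replicate 14 alone had 97, and without it the means were 1.96 ± 4.50 (SD, n = 28) with and 4.17 ± 10.7 without tamoxifen, the opposite direction (two-sided permutation p = 0.372). Of 194 genes that were outliers in any tumour, 27 were outliers in both groups. All others but Foxd1, Gm14964 and Hmox1 were outliers in a single tumour, so they could not be in both. Distances to the group's mean profile averaged 1.07 ± 0.30 and 1.09 ± 0.25 on the log2 CPM scale (two-sided permutation p = 0.825, and 0.827 within title periods). Reads of the transposon construct were present in all 59 tumours, at 9.68 ± 16.7 RPM (reads-per-million) with tamoxifen and 13.9 ± 40.4 without (two-sided permutation p = 0.672, and 0.677 within title periods). The highest were no tamoxifen replicates 13 and 14, at 201 and 109 RPM, and the medians were 2.78 with and 2.22 without tamoxifen. Without no tamoxifen replicate 13 the difference in means went from -4.18 to 2.28 RPM.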

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

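The tests on the label of the disputed library, on other cell types and on the sterol genes, and the counts of splits, were chosen only after those results were seen, while those on the marker scores within groups and on the title dates were fixed before.

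The pericyte and fibroblast score of wild-type replicate 1 in the Math1-Cre; SmoM2 tumours was 3.75, below the 4.33 to 4.67 of the other 6 libraries labelled wild-type. Chance marks about 1 in 20 such measures, and 33 were looked at.

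The low Kcnb2 level in the library labelled wild-type replicate 3 may come from a wrong label. Near Kcnb2 on chromosome 1 (within 10 Mb in GRCm38), 7 of 106 genes separated the knockouts from the other 6 wild-type libraries at an unadjusted p under 0.01, and 5 of these 7 lay nearer the knockouts in this library, against 16.8% of 678 such genes elsewhere. Gm37138, inside the span of Kcnb2, had 23 reads there, 32 to 50 in the knockouts and 0 to 3 in the other wild-type libraries, while Mcmdc2 had 0, 2 to 8 and 17 to 64. This library had more markers of other cells than the other 2 wild-type libraries with numbered titles (choroid plexus score 5.41 against 1.61 and 3.00, oligodendrocyte 5.49 against 3.46 and 2.97, microglia 4.86 against 4.27 and 4.28), but dilution by them is argued against as the whole cause, since Hedgehog targets were not lower there (median log2 difference 0.10, against -2.29 for Kcnb2). The same count in other wild-type libraries was 0 or 1, except in wild-type replicate 1, with 15 of 20, which, like wild-type replicate 4, also lay nearer the knockouts for most genes elsewhere (84.0% and 71.2%).

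The rise of oligodendrocyte, Purkinje and astrocyte markers in the tamoxifen group is consistent with more adjacent cerebellum in those samples: oligodendrocyte and Purkinje scores went together within each group, with the lower r at 0.917. A lower share of tumour cells that lifts all other cell types alike is argued against, since the highest median among endothelial, microglia and pericyte lists was 0.12, against 1.43 for oligodendrocytes. The division into earlier and later titles is argued against as the whole cause, since the median over all 3 lists was 1.30 in the later and 1.33 in the earlier titles. Within the later titles the tamoxifen tumours tended to carry the earlier dates, so an effect of date inside that period is not excluded. Whether tamoxifen changes how much cerebellum surrounds or mixes with a tumour, or how much of it was taken, was not tested. Of 100 splits of the 59 tumours, the real one gave the most genes, 501 against at most 291. This argues against chance for the number over all 59 tumours, but 100 splits cannot show a share under 1 in 100. The number fell to 110 up and 28 down without tamoxifen replicate 14, for which no splits were drawn. For the number of lists chance cannot be excluded, since 32 of 100 gave as many as the real 7, up to 14.

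Scd2, Rnf145, Scd1 and Acsl3 had the 4 smallest p values in the tamoxifen comparison. With Abca1 and Abcg1 they make the 6 sterol and fatty acid genes first seen. The rise of these 6 did not go wholly with adjacent cerebellum as the cell type scores measure it. With the 3 cell type scores as covariates their median was 0.36 ± 0.17 (SD over genes), against 0.55 ± 0.34 without them, and Scd2, Abca1 and Rnf145 were the 3 genes still called. Scd1 went from 1.22 ± 0.20 (SE) to 0.46 ± 0.15 there and lost its call. Scd2 (0.50 to 0.31), Abcg1 (0.60 to 0.35) and Acsl3 (0.32 to 0.20) rose less too, while Abca1 stayed at 0.71 and Rnf145 went from 0.29 to 0.37. Part of the rise of Scd1, Scd2, Abcg1 and Acsl3 thus goes with the scores. The 6 were picked from these same data, and the scores may not take up all adjacent cerebellum, which is therefore not excluded. No gene is shared by the score lists and these 6. Higher activity of LXR, the oxysterol receptor, remains open as a hypothesis, since it was tested only on genes whose values had been seen.

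For the knockout, the 6 libraries with numbered titles make 10 splits, too few for a share under 0.05. All 10 called no gene, the highest other being 0, and the real split called 9 lists where the highest other called 10, with 3 of 10 at 9 or more. Another split gave 3960 genes at an unadjusted p under 0.05 against 1683 in the real one, so the libraries also differ in ways other than the genotype label.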

How the results depend on the processing

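The tests with left-out tumours for tamoxifen, the cell type covariates, the transposon reads and the joint changes of the disputed library and the title covariate were chosen after seeing the data. No paired analysis was possible because replicate numbers follow accession order and pair nothing. For the knockout, no gene was called in edgeR under each other setting or with any 1 library left out (range 0 to 0 up and down), except 2 up, Gm21168 and Gm37138, with the disputed library as a knockout and no title covariate, and DESeq2 gave 4 up and 5 down. Kcnb2 stayed lower throughout, from -1.05 to -1.82 with 1 library left out. Lists called were 1 with an estimated correlation, 0 with fry, and 8 to 10 with 1 library left out.

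For tamoxifen, genes up and down were 769 and 144 in DESeq2, 814 and 349 in limma-voom, 147 and 4 at an absolute log2 fold change of 1 or more, 0 and 0 in the earlier titles, 2 and 0 in the later titles, 9 and 2 with surrogate variables, and 3 and 0 with the cell type scores. Fits within periods also hold fewer tumours, and the causes of these losses were not tested. With 1 tumour left out, 110 to 682 genes were up and 28 to 131 down, and 6 to 7 lists were called. The number down left the range within 1.5 times 81 without tamoxifen replicates 14, 17, 19, 22, 20, 7, 29, 11 and 16 (28, 32, 33, 40, 45, 47, 53, 122 and 123) and no tamoxifen replicates 15, 14, 7, 5, 9, 19, 10, 12, 27, 2, 30 and 8 (36, 40, 41, 45, 46, 47, 49, 50, 50, 52, 53 and 131). Lists called were 0 with an estimated correlation and 4 with fry. Kcnb2 reversed to 0.35 in the earlier titles and 0.0338 with surrogate variables, and stayed from -0.16 to -0.08 with 1 tumour left out. Where the filter kept the gene, 252 of the named genes' values for tamoxifen kept direction and call under other settings. Another 150 kept the direction alone, and with 1 tumour left out the counts were 2478 and 160. Foxd1 reversed to 0.10 in DESeq2 and Pvalb to -0.40 with surrogate variables. No difference passed in outlier genes (-0.0816 with the limit at 8 deviations, against 1.37), spread (0.0339 over fewer genes of highest variance, against -0.0163) or transposon reads (0.566 RPM in medians and 0.23 on the log2 scale, against -4.18). With 1 tumour left out these differences ran from -2.20 (without tamoxifen replicate 14) to 2.86 (without no tamoxifen replicate 16), from -0.0560 to 0.0112 (without the same tumours, in turn) and from -6.24 (without tamoxifen replicate 23) to 2.28 RPM (without no tamoxifen replicate 13), and none passed. At at most 8667344 counts per library, genes of few reads, such as most transposon rows, were the least precise.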

Other observations

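The tests on sterol and fat genes, on single tumours and on the unlabelled tumour were chosen after their values were seen, except those on unseen cholesterol synthesis genes and on Kcnb2 levels. Several genes of sterol and fat handling, picked for their small p, were past the threshold in the tamoxifen comparison, some up and some down. Scd2, a fatty acid desaturase, had the smallest p of all genes (log2 fold change 0.50 ± 0.06 SE, adjusted p = 6.1e-07 in edgeR), with small ones also for Rnf145, a sterol-responsive ubiquitin ligase (0.29 ± 0.04), Scd1 (1.22 ± 0.20), Acsl3 (0.32 ± 0.05), Abca1, a cholesterol exporter (0.71 ± 0.13), and Abcg1 (0.60 ± 0.13). The apolipoprotein genes Apoc1 (1.18 ± 0.24) and Apoe (0.38 ± 0.11) and the lipid gene Mid1ip1 (0.41 ± 0.09) rose too, the 3 past the threshold among 11 other LXR targets. The cholesterol synthesis genes Sqle (-0.33 ± 0.07) and Mvd (-0.37 ± 0.10) fell, as did Stard4, which carries cholesterol in the cell (-0.33 ± 0.09). All 6 genes first seen stayed past the threshold with 10 surrogate variables, where 11 genes were called in all. Since the 6 were picked from these same data, their staying is no independent support.

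A hypothesis is that oxysterol signalling was higher in tamoxifen tumours, with LXR targets up and SREBP2 targets down; tamoxifen is known to block late enzymes of cholesterol synthesis. The 11 other LXR targets were higher in 10 (median 0.31). Their values had been seen before they were tested, so the camera p = 0.000833 decides nothing, and higher LXR activity stays open. On adding the cell type scores as covariates, camera's p for these 11 was 0.0389, in the same direction. Apoe then went from 0.38 to 0.02 and Apoc1 from 1.18 to 1.00, and neither was called. The 15 cholesterol synthesis genes not looked at before were lower in 13 (median -0.17, camera p = 0.0356 with an estimated correlation), a test fixed before they were seen. That p was the largest of the 4 sterol lists, so adjustment over them leaves it unchanged and adds no support. Within the earlier titles p was 0.00470 and within the later ones 0.234, both lower. With the cell type scores as covariates the p of the synthesis genes was 0.136, again lower in direction. This p alone cannot tell a smaller fall from a less precise fit, so whether the fall goes with adjacent cerebellum stays open. When tamoxifen was last given before sampling is not known here, and a direct effect of the drug cannot be set apart from one of the second transposition.

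Single tumours held large rises of single genes, as values with no explanation, again chosen after they were seen. Tle6 lay 8.20 above the median of the 59 tumours on the log2 CPM scale in no tamoxifen replicate 3, and Col6a3 7.07 above it in tamoxifen replicate 28. Foxd1 lay 6.28 and 5.68 above it in no tamoxifen replicates 21 and 17, and Runx2 4.51 above it in no tamoxifen replicate 21. Cdkn2b, a cell cycle inhibitor, lay 4.28 above it in tamoxifen replicate 12, and Hmox1 4.61 above it in tamoxifen replicate 27. The choroid plexus genes Enpp2 and Kl were 5.44 and 5.22 above it in no tamoxifen replicate 6 and 5.16 and 5.06 above it in tamoxifen replicate 6. Of the 59 tumours, 27 had no outlier gene.

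The tumour without a treatment label had 42.4 RPM of transposon reads, and 4 of the 59 labelled tumours had more. The Exon_1 row gave 196 of its 320 transposon reads.

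Before the values were seen, Kcnb2 was expected to go with the division or maturation of the tumour cells across the 59 Lazy Piggy tumours. None of the 3 relations passed. For the cell cycle score Pearson r was -0.0125 (permutation p = 0.925), for the stem and progenitor score -0.15 (permutation p = 0.249) and for the granule neuron score 0.0416 (permutation p = 0.752). Adjusted over the 3, p was 0.925, 0.746 and 0.925. Spearman's rho was -0.18, -0.22 and 0.03 (permutation p = 0.169, 0.0896 and 0.810), and r without the 2 tumours of most extreme Kcnb2 was 0.04, -0.10 and -0.03. With and without tamoxifen, r was 0.15 and -0.32, 0.12 and -0.37, and -0.11 and 0.24, opposite in sign each time, a difference that was not tested. In the earlier and later titles r was -0.10 and 0.04, -0.15 and -0.13, and 0.03 and 0.04.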
